A study of Mus musculus with 4 samples.

How the data were processed

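RNA of splenic naive T cells, WT or KO, kept for 3 days under Treg-inducing conditions was measured on 4 single-colour Affymetrix arrays. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was prepared from 6 micrograms of it by the standard protocol of the manufacturer. The deposited values are linear probe set intensity values, 1 column per array, with MAS5 named in the submitters' processing notes and its version and settings not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set, a group of short probes for 1 transcript, into 1 signal. The values themselves show how the arrays were scaled: after leaving out 2% of the probe sets at each end, the mean was the same on every array. The values were not log-transformed, and array medians lay between 56.5 and 62.6, so no quantile normalization had been applied. Such scaling removes any difference in total RNA per cell between the groups. Dim MAS5 signals vary strongly between arrays, which widens the error of low-expressed genes. The scanner files were not used here.

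The table held 45101 probe sets. Gene names came from the annotation of the array platform, in which 34958 probe sets name 1 gene, 932 several and 9211 none. Gene identifiers of 34754 of the named probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols, and 204 were not found in it. No gene was named from a probe set with several names. Cross-hybridising probe sets were kept, and signals of granzymes, mast cell proteases and immunoglobulin genes can be shared between close relatives of these families. Coordinates were not used here.

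Samples were grouped by the genotype in their titles, as 2 WT and 2 KO arrays. After 64 control probe sets were left out, log2(signal + 16) was computed, and the 40% of probe sets with the lowest mean over all 4 arrays were left out, which left 27022 probe sets for 12547 genes. KO was compared with WT in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, a two-sided moderated test, and the Benjamini-Hochberg adjustment over all tested probe sets at a threshold of 0.05. The residual degrees of freedom were 2 and the prior ones 6.41, so each test borrowed most of its information on the spread from other probe sets. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333. A fold change is on the log2(signal + 16) scale and understates changes of dim genes. Called means past the threshold, and a gene is said to have risen or fallen only where it was called. The median log2 fold change of all tested probe sets was -0.079, and values are given without correction for it.

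For gene lists, 1 probe set per gene was used, the one with the highest mean. The 29 lists with at least 5 tested genes, covering Treg and other helper programmes, signalling, proliferation, metabolism, stress and markers of other cell types, were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. With the correlation estimated, camera has only the 2 residual degrees of freedom, so it had little power to call a list here. The lists hold 606 genes together with a sex-linked list that was given as values, of which 560 had a probe set naming them alone and 528 were tested. Adjustments over the list alone used the tested members of that list.

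The groups, the test, the filters, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named, in each direction, the 12 genes with the largest absolute log2 fold change among called probe sets of 1 gene with non-overlapping groups, every measured Treg signature gene, up to 4 genes with the smallest p of each other list, and the sex-linked genes. Other genes were named after their values were seen, because a count of 5 or fewer in a list called for its names or because they are well known in these programmes. Ifng, Tbx21, Il4, Il17a, Gata3 and Bcl6 are of the second kind. For 71 of the named genes over 1 probe set was tested, and 0 of them had calls in opposite directions.

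The alternatives were a pseudocount of 1 or 64, no filter or a filter of 60%, quantile normalization, centring of each array on its median, no intensity trend, the array number as a block, leaving out probe sets marked as cross-hybridising, and leaving out each array in turn. The fit and the camera test were checked on simulated data with the means of the 27022 tested probe sets, 2 against 2 arrays, and variances drawn from the fitted prior. Only 200 probe sets were changed and the noise was independent, so the shares may differ where more probe sets change. Of 50 probe sets changed at each size, 2% were called at a log2 change of 0.5, 20% at 1, 64% at 2 and 80% at 3, all in the right direction, and 2 of 85 calls were false. Variances were drawn in 3 ways, and the one used was chosen after the false calls of all 3 were seen: 39 of 164 calls were false with the posterior variances of the fit, 0 of 46 with the raw residual variances. The chosen draw is the distribution that the model assumes, so it checks the code and says little of how the test fares when that assumption fails. With the posterior variances the share of false calls, 23.8%, was above the threshold of 0.05, so the adjusted p-values may understate the share of false calls. Of the simulated lists of 20 genes, the 1 list shifted by 0.5 was called and 0 of 19 others were. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.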

Results

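The data compared T cells of KO mice with T cells of wild-type (WT) mice, in order to find the genes whose expression differs between the genotypes after induction of regulatory T cells (Treg cells). Treg cells are a CD4 T cell lineage that restrains immune responses and depends on the transcription factor Foxp3. Naive T cells from spleen had been cultured for 3 days under Treg-inducing conditions, and their RNA was measured on 4 single-colour Affymetrix arrays, 2 of WT and 2 of KO cells. The labels do not name the gene removed in the KO, so its level is not reported. Each array is labelled with its own numbered source of mice, and the labels say no more on how the cultures were kept apart. The p-values therefore measure the spread between these samples, which may be partly technical. Signals are MAS5 values, scaled to the same trimmed mean on every array. Over the 27022 probe sets tested, the log2 signals of the 2 WT arrays correlated at r = 0.979 and those of the 2 KO arrays at r = 0.977, while arrays of different genotype correlated at 0.933 to 0.941. These are correlations across probe sets, which are not independent replicates. Signals differed by 2-fold or more at 4.85% of probe sets between the WT arrays, at 5.49% between the KO arrays, and at 12.8% to 16% between arrays of different genotype. The number of arrays limits the precision of all values.

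Several transcripts of granule proteins that were dim in WT cells rose in KO cells, and a set of transcripts that WT cells expressed at moderate to high level fell. Mcpt1, a mast cell chymase, rose from 46.8 ± 7.82 in WT to 10795 ± 4208 in KO cells (signal, mean ± SD, n = 2 per group), a fold of 166 on the log2(signal + 16) scale and a log2 fold change of 7.38 ± 0.25 (± SE, limma, adjusted p = 3.26e-06). Il10, which encodes an anti-inflammatory cytokine, rose from 62.8 ± 27.7 to 4894 ± 46.0, or 64.3-fold (adjusted p = 5.01e-06). Ntn4, a netrin, fell from 848 ± 10.8 in WT to 24.8 ± 16.6 in KO cells, with a WT signal 22.1 times that of KO cells on the same scale (log2 fold change -4.47 ± 0.31, adjusted p = 6.54e-05). Atp1b1, a sodium pump subunit, fell from 10586 ± 967 to 814 ± 21.6, or 12.8-fold (adjusted p = 2.39e-06). In all, 4608 of 27022 probe sets passed an adjusted p of 0.05 (17.1%), of which 2131 were higher and 2477 lower in KO cells. They represent 1513 genes called higher and 1597 called lower, with 25 genes among both.

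The large changes were mostly rises. Among the called probe sets, 1165 rose and 935 fell by 2-fold or more, and 192 rose and 21 fell by 8-fold or more. The 12 genes with the largest rises included the mast cell or basophil proteases Mcpt1, Mcpt2 (7.13 ± 0.71), Cpa3 (6.09 ± 0.24) and Mcpt8 (5.98 ± 0.48), where values in parentheses are log2 fold changes ± SE. They also included Prg2, which encodes the eosinophil major basic protein (6.86 ± 0.39), the protease gene Ctsg (5.53 ± 0.39), the granzymes Gzmd (5.90 ± 0.63) and Gzme (5.46 ± 0.64), and Timp1 (6.38 ± 0.21), an inhibitor of matrix metalloproteinases. Jchain (5.40 ± 0.29), which links immunoglobulin units, and the lambda variable gene Iglv1 (5.38 ± 0.60) completed this group together with Il10. Their WT signals were low, so the folds depend on the added 16 and understate the ratios of the raw signals. With a pseudocount of 64 all 12 were smaller by over 1.5 times, and the log2 fold change of Prg2 was 9.01 with 1 and 5.16 with 64. The 12 largest falls were those of Ntn4, Dapl1 (-4.43 ± 0.32), Pdlim4 (-3.84 ± 0.12), Atp1b1, the extracellular matrix gene Fbln1 (-3.57 ± 0.35), Mtus1 (-3.55 ± 0.24), Capn3 (-3.37 ± 0.53), Bex1 (-3.20 ± 0.26), Itih5 (-3.14 ± 0.14), Ltbp1 (-3.02 ± 0.41), Drc1 (-2.97 ± 0.17) and Trim43a (-2.91 ± 0.58). Of the 24 genes, which the rule took only from non-overlapping groups, the calls of Gzme, Capn3, Ltbp1 and Trim43a were lost when the variance was fitted without its dependence on intensity. That of Trim43a was also lost without WT array 1. Some sizes hang on single arrays. WT array 2 had more Mcpt2 than WT array 1 (270.1 against 23.8), and likewise more Mcpt8, Gzmd and Gzme, but less Iglv1. Leaving out either WT array moved the folds of these 5 genes and of Trim43a by over 1.5 times, that of Mcpt2 to a log2 fold change of 5.71 or 8.56. Leaving out either KO array did so for Prg2, Iglv1, Capn3, Ltbp1 and Trim43a, and a pseudocount of 64 for the falls of Ntn4, Dapl1, Fbln1, Mtus1, Capn3, Ltbp1 and Trim43a. The counts are open to that choice as well: without the intensity trend 1183 probe sets were called, 727 higher and 456 lower. Leaving out WT array 1 gave 3032 calls, and leaving out WT array 2 gave 2786. In simulated arrays of the same design 0% to 23.8% of calls were false, depending on how the variances were drawn. Only 200 probe sets were changed there and the noise was independent, so this range does not carry over to the calls in the data.

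**Figure D1:**
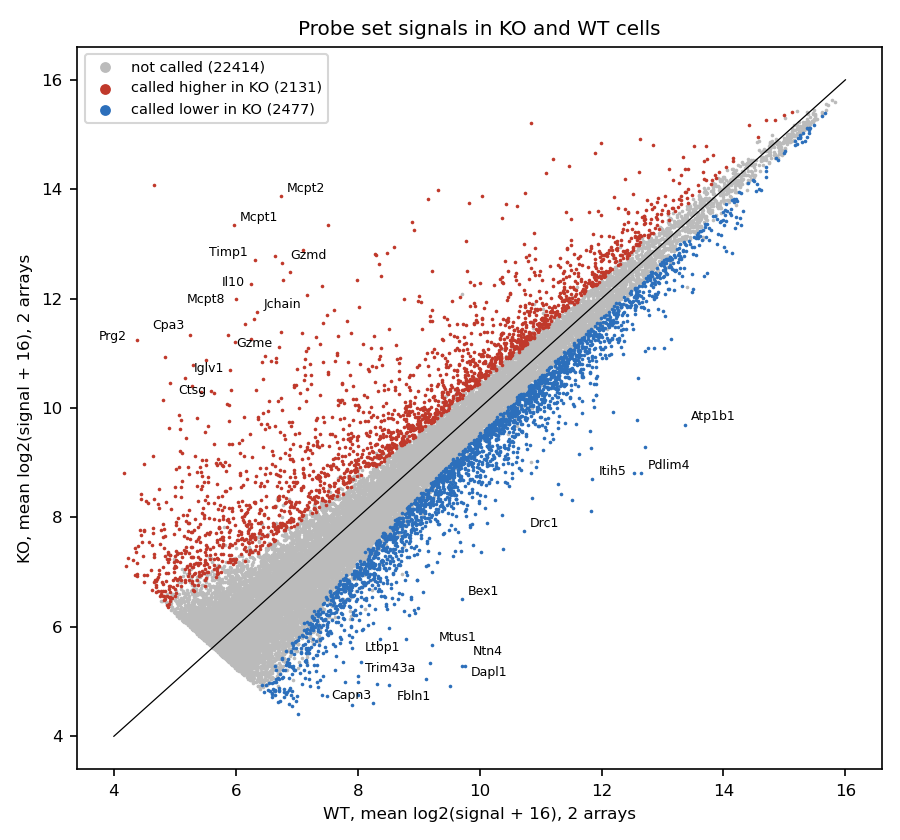
Mean log2(signal + 16) of the 2 KO arrays (vertical axis) against that of the 2 WT arrays (horizontal axis), 1 point per tested probe set, with the 2131 probe sets called higher in red, the 2477 called lower in blue and the line of equal signal in black. Of the 24 named genes, those with the largest called changes among probe sets of 1 gene, Mcpt1, Prg2 and Cpa3 lie at the left edge, far above the line, and Atp1b1 and Pdlim4 lie below it among brighter probe sets.

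Genes of the Treg signature moved in both directions in KO cells. Foxp3 fell from 2105 ± 102 in WT to 1024 ± 109 in KO cells, or 2.04-fold (log2 fold change -1.03 ± 0.13, adjusted p = 0.00123). Nrp1, a semaphorin co-receptor, fell from 2472 ± 266 to 1017 ± 235 (adjusted p = 0.0016), and the transcription factor genes Ikzf2 (-0.73 ± 0.15) and Ikzf4 (-0.51 ± 0.11) fell by less. Gpr83 (-1.07 ± 0.13), Izumo1r (-0.91 ± 0.11), a folate receptor relative, and Socs2 (-0.96 ± 0.14), a suppressor of cytokine signalling, were the other 3 of the 7 members that fell. In the same samples Il10 rose, the inhibitory receptor gene Lag3 rose from 127 ± 5.19 to 1106 ± 98.2 (7.85-fold, adjusted p = 2.91e-05), and the costimulatory receptor gene Icos rose from 4727 ± 506 to 14926 ± 819.5 (3.16-fold, adjusted p = 4.1e-05). The other rises were those of Nt5e (1.93 ± 0.14) and Entpd1 (1.97 ± 0.19), the ectoenzymes that make extracellular adenosine, of Tnfrsf9 (1.62 ± 0.16), Klrg1 (1.99 ± 0.33), Il2ra (0.99 ± 0.12), Ctla4 (0.97 ± 0.10), Itgae (0.55 ± 0.12), Tnfrsf18 (0.50 ± 0.09), Tnfrsf4 (0.49 ± 0.09) and Capg (0.40 ± 0.09). Ccr8 (0.65 ± 0.25), Tgfb1 (0.51 ± 0.15) and Ebi3 (0.30 ± 0.16) did not pass. Thus 13 of 23 tested members rose, 7 fell and 3 did not pass, and 15 rose and 7 fell when adjusted over the list alone. As a list the signature lay above the other genes (adjusted p = 0.00164, camera), which was lost with its own correlation estimated (adjusted p = 0.365 with an estimated correlation). Without the intensity trend 7 members remained called, all higher (Il10, Lag3, Icos, Nt5e, Entpd1, Tnfrsf9 and Klrg1), and Foxp3 was at an adjusted p of 0.0518 with the same log2 fold change. Testing all probe sets with no filter ended the call of Itgae. Leaving out WT array 1 ended those of Tnfrsf18, Tnfrsf4, Capg and Itgae, and leaving out WT array 2 those of Ikzf2, Ikzf4 and Capg. With a pseudocount of 64 the rise of Klrg1 was smaller by over 1.5 times.

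**Figure D2:**
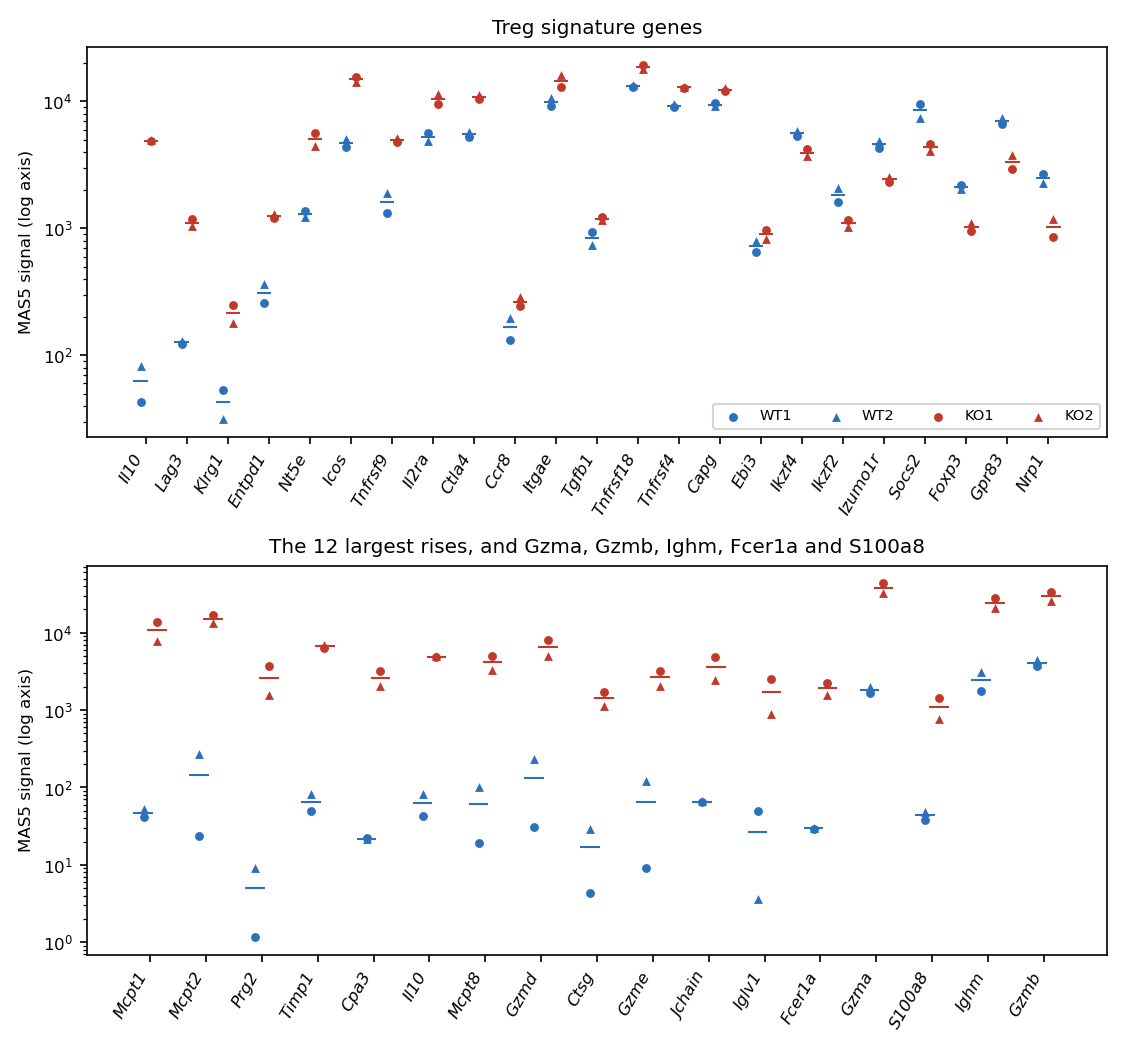
MAS5 signal on a log axis in the 2 WT arrays (blue) and the 2 KO arrays (red), circles for number 1 and triangles for number 2, with short lines at the group means. The upper panel holds the 23 tested Treg signature genes in order of log2 fold change, from Il10 at 6.01 to Nrp1 at -1.28, and the lower panel the 12 largest rises and 5 further called genes, all with KO arrays above WT arrays.

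Many genes of the other helper T cell programmes rose in KO cells. The granzyme gene Gzma rose from 1836 ± 250.2 in WT to 38088 ± 7726 in KO cells (20.5-fold, adjusted p = 3.3e-06), the granzyme gene Gzmb from 4089.6 ± 565 to 29584 ± 5425 (7.18-fold), and the interferon-gamma gene Ifng from 1810.0 ± 519 to 7120.5 ± 554 (3.98-fold, adjusted p = 0.00023). Of 19 tested members of the Th1 and cytotoxic list 15 rose, among them the chemokine gene Ccl4 (3.82 ± 0.14), the interleukin-12 receptor gene Il12rb1 (3.42 ± 0.20) and the lineage factor gene Tbx21 (1.33 ± 0.19). 2 members fell, Stat4 (-0.70 ± 0.14) and Il18r1 (-0.41 ± 0.09), and Eomes and Il12rb2 did not pass. Of the markers of CD8 T cells 6 of 7 rose too, with Cd8a (1.78 ± 0.18), and of NK cells 5 of 7, and Gzma, Gzmk and Ccl5 are on these lists as well. The list was called up (adjusted p = 4.39e-12; adjusted p = 0.365 with an estimated correlation), and 17 and 2 members were higher and lower when adjusted over the list alone. Of 13 tested Th2 genes 10 rose and none fell, including Maf (4.02 ± 0.18), the cytokine genes Il9 (3.92 ± 0.20) and Il4 (2.82 ± 0.41), and the transcription factor gene Nfil3 (1.43 ± 0.11), besides Il10. Gata3, the Th2 lineage factor, was at -0.36 ± 0.13 and did not pass (adjusted p = 0.0962), nor did Epas1 and Gfi1. The Th2 cytokine genes Il4, Il13 and Il5 were higher on KO array 1 than on KO array 2, by log2 differences of 1.27, 1.39 and 0.66, as were the eosinophil genes Prg2 (1.23) and Epx (1.90), while Maf (-0.17) and Il9 (-0.40) were not. Il5, Il13 and Epx were picked for this after their values were seen. For Th2 the camera test gave adjusted p = 6.03e-07 and adjusted p = 0.365 with an estimated correlation, with 10 and 1 members higher and lower when adjusted over the list alone. Of 13 tested Th17 genes 10 rose, including the galectin gene Lgals3 (3.30 ± 0.17), the aryl hydrocarbon receptor gene Ahr (2.53 ± 0.20), Il21 (3.25 ± 0.28), Il1r1 (3.71 ± 0.34) and Il17a (2.77 ± 0.41), and Il6ra (-0.92 ± 0.19) fell, while Csf2 and Ccr6 did not pass. Th17 was called up (adjusted p = 1.44e-06; adjusted p = 0.365 with an estimated correlation), with 11 and 2 members higher and lower when adjusted over the list alone. The follicular helper list moved both ways. 7 of its 12 tested members rose, including Tox2 (2.50 ± 0.20), Il21, Cxcr5 (2.40 ± 0.27) and Cxcr4 (0.996 ± 0.12), and 3 fell, namely Slamf6 (-0.93 ± 0.17), Tox (-0.84 ± 0.21) and the lineage factor gene Bcl6 (-0.78 ± 0.19). Btla and Sh2d1a did not pass. That list was called up (adjusted p = 0.0286; adjusted p = 0.393 with an estimated correlation), with 7 and 4 members higher and lower when adjusted over the list alone. Without the intensity trend, or without cross-hybridising probe sets, the follicular helper list lost its call. Without the trend so did Tbx21, Il4, Il17a, Cxcr4, Bcl6, Stat4, Il18r1, Il6ra, Slamf6 and Tox. Leaving out certain single arrays, or testing all probe sets with no filter, also ended the calls of Bcl6 and Tox, leaving out either WT array that of Il18r1, and leaving out WT array 2 that of Stat4. Il1r1 was at 6.39 and 8.97 on the WT arrays, and its log2 fold change was 5.10 with a pseudocount of 1 and 2.32 with 64, while with 64 Il21 was at 2.45 and the fold of Il4 also fell by over 1.5 times. Single WT arrays moved the fold of Il17a, and single KO arrays that of Il4, by over 1.5 times.

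Many genes of naive and resting T cells fell. Klf2, a factor that maintains quiescence and lymph node homing, fell from 11420.4 ± 850.2 in WT to 4469 ± 160.2 in KO cells (2.55-fold, adjusted p = 8.05e-05), the Wnt pathway factor gene Lef1 fell from 16891 ± 469 to 7469.8 ± 487 (2.26-fold, adjusted p = 0.000108), and Dapl1 fell 21.5-fold. Il7r, the interleukin-7 receptor gene, went the other way and rose from 2902 ± 578 to 11328 ± 1544 (3.91-fold, adjusted p = 0.000107), and so did Satb1 (0.67 ± 0.10). Of the 19 tested members 9 fell, 2 rose and 8 did not pass, and 3 rose and 11 fell when adjusted over the list alone. As a whole it was called down (adjusted p = 0.000541; adjusted p = 0.365 with an estimated correlation). Activation genes split. Cd44 (1.47 ± 0.10), Irf4 (1.48 ± 0.12) and Il2 (0.97 ± 0.24) rose, 9 members fell, including the orphan nuclear receptor gene Nr4a3 (-1.10 ± 0.12) and the inhibitory receptor gene Cd5 (-0.82 ± 0.09), and 10 of 22 did not pass. With adjustment over the list alone 6 and 9 were higher and lower. The list was not called (adjusted p = 0.553), and its median (0.06) and mean (-0.05) differed in sign, with the test pointing down.

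Several genes of the interleukin-2 and STAT5 response list rose, while others hardly moved. Prdm1, which encodes the repressor Blimp-1, rose from 194 ± 64.1 in WT to 1131 ± 180.5 in KO cells (5.55-fold, adjusted p = 0.00031), and Gadd45g (1.82 ± 0.18), Ptger2 (1.89 ± 0.20) and the cytokine gene Lif (1.14 ± 0.13) rose too. Of 19 tested members 10 rose, 1 fell (Socs2) and 8 did not pass, with 10 and 1 higher and lower when adjusted over the list alone. Among those that did not pass were Cish (-0.046 ± 0.135), Pim1 (0.026 ± 0.090), Bcl2 (-0.213 ± 0.123) and Bcl2l1 (0.001 ± 0.145). The list's rise was thus not shared by all its members. The list was called up (adjusted p = 0.00164; adjusted p = 0.365 with an estimated correlation). Of 24 interferon response genes 7 rose, including the GTPase gene Iigp1 (1.74 ± 0.12), Isg20 (1.59 ± 0.15), Zbp1 (1.27 ± 0.14) and Usp18 (1.18 ± 0.14). Ifit2 (-0.63 ± 0.14) fell and 16 did not pass, and 9 and 3 were higher and lower when adjusted over the list alone. This list was called up (adjusted p = 0.00409; adjusted p = 0.365 with an estimated correlation). Of 18 TGF-beta response genes 7 rose, including Id2 (1.70 ± 0.14), Tgfbi (3.39 ± 0.34), Junb (1.03 ± 0.12) and the cell cycle inhibitor gene Cdkn2b (2.25 ± 0.29). The corepressor genes Ski (-0.52 ± 0.10) and Skil (-0.37 ± 0.10) fell, and 9 did not pass. With adjustment over the list alone 7 and 5 were higher and lower, and the list was not called (adjusted p = 0.0767), though it passed by fry (adjusted p = 0.0276) and without WT array 1, WT array 2 or KO array 1. A pseudocount of 1 or 64 moved the fold of Tgfbi by over 1.5 times. Of 17 NF-kappaB response genes Traf1 (2.28 ± 0.17) rose, Cd83 (-1.59 ± 0.20) and Nfkbid (-0.96 ± 0.12) fell and 14 did not pass, the same counts as when adjusted over the list alone, and the list was not called (adjusted p = 0.943). Without the intensity trend the calls of Satb1, Cd5, Il2, Junb, Lif, Ifit2, Ski and Skil were lost. Those of Il2, Ifit2, Ski and Skil also ended when certain single arrays were left out, and the interferon list was not called by fry (adjusted p = 0.0636).

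Many genes of DNA replication were lower in KO cells. Mcm2, a subunit of the replicative helicase, fell from 2597 ± 464 in WT to 1437 ± 166 in KO cells (1.79-fold, adjusted p = 0.0073), and Cdt1 (-0.80 ± 0.14), Rpa2 (-0.67 ± 0.12) and Mcm7 (-0.69 ± 0.13) fell as well. Of 29 tested members 12 fell, none rose and 17 did not pass, and 19 fell when adjusted over the list alone. Camera called the list down (adjusted p = 2.74e-05; adjusted p = 0.503 with an estimated correlation). Of 29 mitosis genes none passed in either direction over all genes or when adjusted over the list alone, although the list was called down (adjusted p = 0.02; adjusted p = 0.812 with an estimated correlation) at a median log2 fold change of -0.26. Its smallest p belonged to Kif23, a mitotic kinesin gene at -0.54 ± 0.16 (adjusted p = 0.0541). Without KO array 2 the mitosis list had a median of -0.008 and no call, and without WT array 1 it was not called either. By fry neither list was called. The 4 named replication genes lost their calls without the intensity trend.

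Metabolic lists moved little. Of 21 glycolysis genes 4 rose, none fell and 17 did not pass. Those 4 were not glycolytic pathway enzymes alone: Hif1a, the hypoxia-inducible factor gene, rose from 5446 ± 1619 in WT to 18737 ± 857 in KO cells (3.51-fold, adjusted p = 0.000319), beside the glucose transporter gene Slc2a3 (0.65 ± 0.09), hexokinase 2 (0.49 ± 0.10, Hk2) and the lactate transporter gene Slc16a3 (0.76 ± 0.21). The list was called up at a median of 0.13 (adjusted p = 0.0477; adjusted p = 0.365 with an estimated correlation), with 4 higher when adjusted over the list alone, and its call ended without either WT array, without the intensity trend or without cross-hybridising probe sets. Of 34 oxidative phosphorylation genes Ndufa4 (-0.40 ± 0.11) fell and 33 did not pass, and none passed when adjusted over the list alone (adjusted p = 0.553). Of 20 fatty acid oxidation genes Acadl (0.72 ± 0.12) rose, Acaa2 (-0.56 ± 0.11) and Echs1 (-0.48 ± 0.12) fell and 17 did not pass (adjusted p = 0.84), with 2 and 3 higher and lower when adjusted over the list alone. Their median (0.04) and mean (-0.03) differed in sign. Of 25 sterol and lipid synthesis genes Lss (1.08 ± 0.16) and Elovl6 (0.68 ± 0.17) rose, Stard4 (-0.69 ± 0.13) fell and 22 did not pass, with the same counts when adjusted over the list alone (adjusted p = 0.5), and the list was called down only without KO array 2 (adjusted p = 0.0273). Without the intensity trend all of these metabolic calls but that of Hif1a were lost. Those of Hk2, Slc16a3, Ndufa4, Acaa2, Echs1 and Elovl6 also ended when certain single arrays were left out.

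Some genes of the unfolded protein response rose. Sdf2l1 rose from 1701 ± 29.3 in WT to 3805 ± 582 in KO cells (2.21-fold, adjusted p = 0.000708), and the oxidoreductase genes Ero1a (1.01 ± 0.11) and Pdia6 (0.88 ± 0.10) and the chaperone gene Hsp90b1 (0.81 ± 0.12) rose with it. Of 21 unfolded protein response genes 11 rose, Herpud1 (-0.80 ± 0.15) fell and 9 did not pass, among them the chaperone and folding genes Calr, Hyou1, Pdia3 and Pdia4, with 14 and 1 higher and lower when adjusted over the list alone. Camera called this list up (adjusted p = 6.91e-06; adjusted p = 0.45 with an estimated correlation). Some plasma cell genes rose in the same samples, among them Jchain and Ighm. Mzb1 (8.50-fold), Slamf7 (7.34-fold), Sdc1 (3.18-fold), Ell2 (2.81-fold) and Ssr4 (1.39-fold) rose too, and were picked after their values were seen. Txndc5, Sec11c, Derl3, Fkbp11, Eaf2, Tnfrsf13b and Tent5c did not pass and Glcci1 fell, and a link to the unfolded protein response list was not tested. Genes of amino acid supply and the ATF4 response divided, 7 of 26 rising and 6 falling. The serine synthesis enzyme gene Phgdh fell from 13541 ± 1255 to 5672 ± 618 (2.38-fold, adjusted p = 0.000229), the folate cycle gene Mthfd2 (-0.81 ± 0.14) and asparagine synthetase (-0.65 ± 0.12, Asns) also fell, and Cebpb (0.92 ± 0.12) rose. That list was not called (adjusted p = 0.726), had 7 and 8 members higher and lower when adjusted over the list alone, and had a median of -0.11 against a mean of 0.02. Of 19 p53 and apoptosis genes Cdkn1a (0.82 ± 0.10), Pmaip1 (1.48 ± 0.20) and Perp (1.53 ± 0.29) rose and 6 fell, including Zmat3 (-1.11 ± 0.14) and Sesn1 (-1.67 ± 0.24), while 10 did not pass (adjusted p = 0.065), with 3 and 7 higher and lower when adjusted over the list alone. The p53 list passed by fry (adjusted p = 0.0494), with no filter and with quantile normalization, each time pointing down. Of 21 heat shock and oxidative stress genes the antioxidant genes Gsr (1.995 ± 0.20), Hmox1 (1.63 ± 0.23), Srxn1 (1.72 ± 0.28) and Gclm (0.58 ± 0.15) rose, Hspe1 (-0.57 ± 0.10) and Gclc (-0.68 ± 0.12) fell and 15 did not pass (adjusted p = 0.208), with 5 and 2 higher and lower when adjusted over the list alone. Without the intensity trend the calls of Sdf2l1, Ero1a, Pdia6, Hsp90b1, Herpud1, Mthfd2, Asns, Cebpb, Cdkn1a, Perp, Sesn1, Hspe1, Gclm and Gclc were lost. Those of Asns and Gclm also ended without WT array 1. By fry the unfolded protein response was not called (adjusted p = 0.075).

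Several genes of trafficking rose, among them the gut-homing chemokine receptor gene Ccr9, from 87.2 ± 28.2 in WT to 1917 ± 169.8 in KO cells (19.1-fold, adjusted p = 1.6e-05), and Cxcr6, from 150.3 ± 13.6 to 2360.0 ± 736 (14.0-fold, adjusted p = 2.51e-05). Cd44 and the integrin gene Itgav (1.14 ± 0.09) rose, and the integrin gene Itga4 (-1.32 ± 0.15) fell. Of 23 tested members 12 rose, 1 fell and 10 did not pass, and 14 and 1 were higher and lower when adjusted over the list alone. The list was called up (adjusted p = 6.03e-07; adjusted p = 0.365 with an estimated correlation). General T cell genes remained bright in all 4 arrays. Cd3g rose from 8822 ± 221 to 21124 ± 569 (adjusted p = 5.29e-05), Cd3e (0.90 ± 0.12), Zap70 (0.63 ± 0.12), Thy1 (0.41 ± 0.10) and Cd3d (0.35 ± 0.09) rose, and Cd5, Cd6 (-0.73 ± 0.11) and Bcl11b (-0.62 ± 0.09) fell. The other 6 of the 14 did not pass and the list was not called (adjusted p = 0.713), with the same counts when adjusted over the list alone. Of these 8 T cell calls only that of Cd3g was kept without the intensity trend, and those of Thy1 and Cd3d also ended without either WT array.

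Most tested markers of neutrophils and mast cells, myeloid cells, CD8 T cells and NK cells rose in KO cells. The filter used the mean over all 4 arrays, so markers dim in WT cells could pass it by being high in KO cells. Of tested markers, 0 of 14 for neutrophils and mast cells and 2 of 17 for myeloid cells lay above the median WT signal. For CD8 T cells it was 3 of 7 and for NK cells 2 of 7. Before the filter the array held 16, 23, 7 and 10 markers of these lists. Among genes outside a further mast cell list, described below, 10.4% were called higher. The mast cell carboxypeptidase gene Cpa3 rose from 21.9 ± 0.626 in WT to 2633 ± 810.5 in KO cells (68.3-fold, adjusted p = 5.1e-06), the IgE receptor chain gene Fcer1a from 29.8 ± 0.654 to 1906 ± 499.8 (41.2-fold, adjusted p = 7.93e-06), and S100a8, a neutrophil and monocyte gene, from 43.6 ± 7.34 to 1092 ± 458 (17.9-fold, adjusted p = 7.97e-05). Of 14 tested neutrophil and mast cell markers 11 rose and none fell, and Mmp9, Elane and Ltf did not pass (adjusted p = 1.08e-09; adjusted p = 0.365 with an estimated correlation). Of 17 myeloid and dendritic cell markers 12 rose and none fell, including the Fc receptor gene Fcgr3 (3.48 ± 0.32), Fcer1g (4.28 ± 0.47), Mpeg1 (2.37 ± 0.35) and Ctss (0.58 ± 0.09), and 5 did not pass, namely Clec7a, Itgax, Fcgr1, Csf1r and Flt3 (adjusted p = 1.44e-06; adjusted p = 0.365 with an estimated correlation). Of 7 CD8 T cell markers Klrd1 (3.31 ± 0.21), Cd8a (1.78 ± 0.18), Gzmk (4.48 ± 0.53), Ccl5, Klrk1 (2.52 ± 0.33) and Cd8b1 (1.02 ± 0.14) rose and Eomes did not pass (adjusted p = 1.3e-06; adjusted p = 0.365 with an estimated correlation). Of 7 NK cell markers Gzma, Klrd1, Klrc1 (3.46 ± 0.33), Fcer1g and Tyrobp (3.14 ± 0.68) rose, Txk (-0.83 ± 0.12) fell and Klre1 did not pass (adjusted p = 0.00019; adjusted p = 0.365 with an estimated correlation), and 4 of the 7 are on other lists as well. When adjusted over each list alone, the higher and lower members were 12 and 0 for neutrophil and mast cells, 13 and 0 for myeloid cells, 7 and 0 for CD8 T cells and 6 and 1 for NK cells.

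Of 18 B cell and plasma cell markers 3 rose, namely Jchain, Ighm (1 of its 3 called probe sets among 6 tested), from 2444 ± 964 to 24294 ± 5292 (10.2-fold, adjusted p = 8.42e-05), and the class II gene H2-Ab1 (1.17 ± 0.20). Spib (-1.88 ± 0.47) fell, 14 did not pass, and 3 and 2 were higher and lower when adjusted over the list alone, with no call of the list (adjusted p = 0.139). That list was called up without WT array 2 (adjusted p = 1.64e-05), without KO array 2 (adjusted p = 0.0467) and with a filter of 60% (adjusted p = 0.0422), and pointed down without WT array 1. Of 7 erythroid and platelet markers the platelet factor gene Pf4 (3.11 ± 0.51), Tal1 (1.81 ± 0.41) and Gp1bb (1.66 ± 0.41) rose, and Car2, Klf1, Itga2b and Slc4a1 did not pass (adjusted p = 0.00866; adjusted p = 0.365 with an estimated correlation), with 4 and 0 higher and lower when adjusted over the list alone. Before the filter the array held 13 markers of this list, and 0 of the 7 tested lay above the median WT signal. Among the markers of other cell types, the calls of Mpeg1, Ctss, Gzmk, Ccl5, Klrk1, Tyrobp, Txk, H2-Ab1, Spib, Pf4, Tal1 and Gp1bb were lost without the intensity trend. Those of Spib, Tal1 and Gp1bb also ended with no filter or without certain single arrays, and the myeloid list was not called by fry (adjusted p = 0.075). Leaving out single arrays moved the folds of Fcer1g, Tyrobp, Spib, Pf4, Gzmk and Ccl5 by over 1.5 times. A pseudocount of 64 did so for Cpa3, Fcer1a, S100a8, Fcer1g, Klrc1, Gzmk, Tyrobp, Pf4, Tal1 and Gp1bb. The Y-linked genes were at 0.385 to 45.5 on all arrays. The brightest Xist probe set was at 5351 to 9880.1, lower in KO cells by a log2 fold change of -0.62 ± 0.14 (adjusted p = 0.0164), a call lost without the intensity trend or without WT array 2. Of signs of RNA quality, the ratio of 3' to 5' signal of the beta-actin control was 1.36 and 1.56 on the WT arrays and 1.26 and 1.22 on the KO arrays, and that of Gapdh 1.02 and 1.07 on the WT arrays and 0.908 and 0.923 on the KO arrays.

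**Figure D3:**
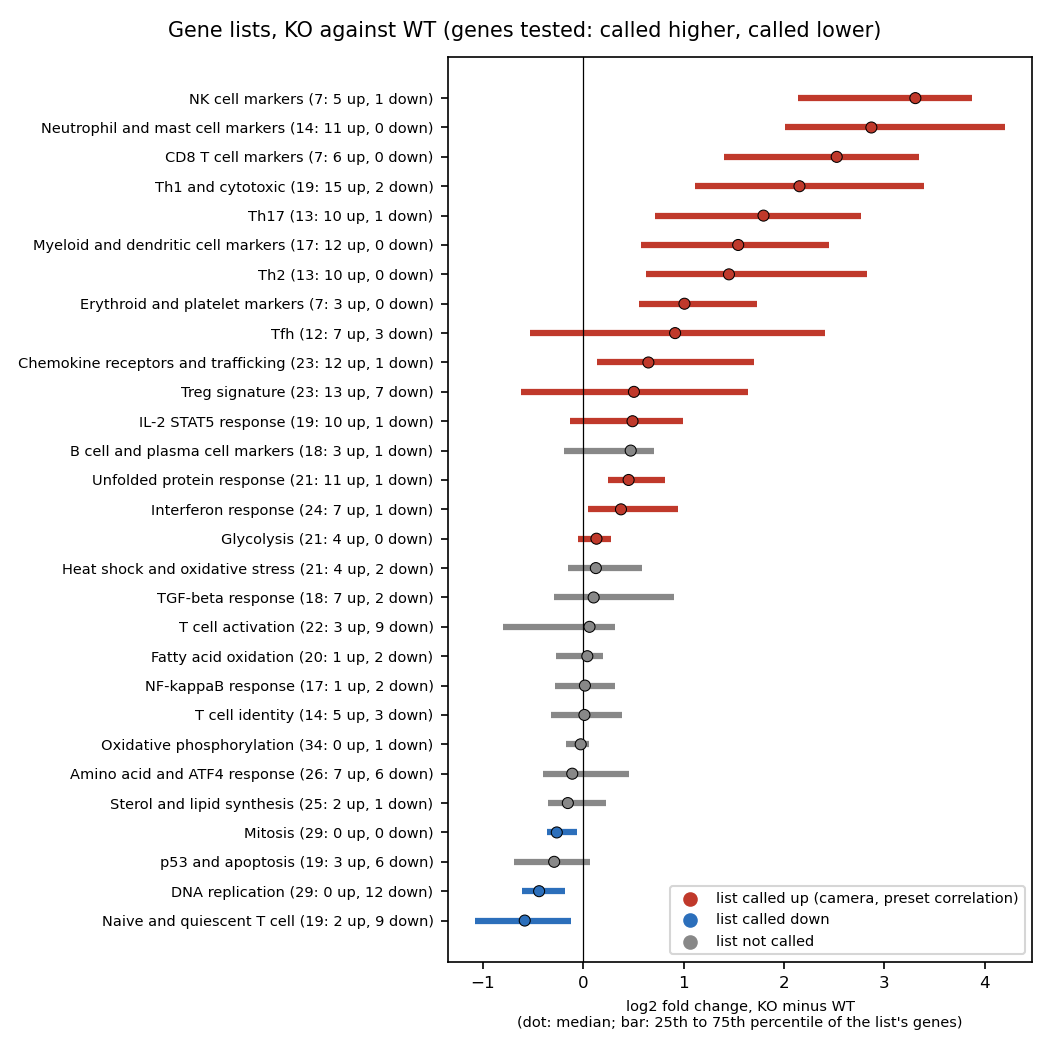
Median (dot) and 25th to 75th percentile (bar) of the log2 fold changes, KO minus WT, of the tested genes of 29 lists, with counts of genes tested and called beside each name, in red for the 15 lists called up and in blue for the 3 called down with a preset correlation. NK cell markers had the highest median, 3.31, and the naive and quiescent T cell list the lowest, -0.58, and 0 lists were called with an estimated correlation.

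Over all 29 lists, 15 were called up and 3 down by camera with a preset correlation of 0.01. With the correlation estimated from the arrays 0 lists were called, none at an unadjusted p under 0.05 either, and the smallest adjusted p was 0.365. That version has little power with 2 residual degrees of freedom, so the lost calls do not show that correlated members had produced them. The IL-2 and STAT5 list had an estimated correlation of -0.053, below the preset 0.01, yet its unadjusted camera p went from 0.000737 to 0.067. By fry, which asks whether a list's genes move one way on balance, 15 lists passed, and in either direction 28 passed.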

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

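The comparison of ribosomal RNA controls was chosen only after their values were seen, and no test was applied to it. The 3 control probe sets for 18S ribosomal RNA, which were outside the tested probe sets, were higher on both KO arrays than on both WT arrays, by log2 differences of 0.40 (3' probe set), 0.336 (5' probe set) and 0.423 (middle probe set), a mean of 0.39. They measure 1 RNA, so they are not 3 separate observations, and groups of 2 arrays lie apart, one way or the other, in 33.3% of cases by chance. Among the tested probe sets 60.2% lay apart, so lying apart is common in these data. Over the 37 spiked controls with a mean signal over 200 the median log2 difference was -0.09.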

How the results depend on the processing

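All alternatives but those on the ratio of the KO arrays and on the shares of the marker test lists, which were chosen after seeing the data, were fixed before the data were examined, and no other test of this part was chosen after its result was seen. Of what was put to them, 39 of the genes and probe sets were picked after their values were seen. Every probe set called and also tested under an alternative kept its direction in all 13 settings. For many settings this was fixed in advance. The filters, the fit without the trend, the block and the removal of cross-hybridising probe sets leave each fold change as it is. Where the groups do not overlap, another pseudocount or a left-out array cannot turn it either. The count of 4608 stayed within 1.5 times, between 3272 and 4844, with a pseudocount of 1 or 64, no filter, the 60% filter, quantile normalization, median centring and without cross-hybridising probe sets. Without the intensity trend it was 1183 (727 higher, 456 lower), of which 1149 were among the 4608, and the share of higher calls was 61.5% instead of 46.2%. This setting uses the same values and fold changes, and gives all probe sets 1 common prior variance. Leaving out 1 array gave 2786 to 4387 calls, 1611 to 1817 higher and 1163 to 2570 lower, with WT array 1 (3032 calls, 1421 lower) and WT array 2 (2786 calls, 1163 lower) moving them most. The lone array is assumed to vary like the other group, and the cause was not tested. Median centring made 52.6% of calls higher. Of the 134 called genes among the 148 chosen by the rule, 77 kept their call in every one of the 13 settings that tested them, and 57 were lost without the intensity trend. Not all were tested in each: 139 of the 148 were measured with the 60% filter and 124 without cross-hybridising probe sets. None turned direction, which most settings could not change. Of the 36 called genes and probe sets named later, 28 lost their call there. The folds of 16 of the called genes moved by over 1.5 times with a pseudocount of 1, of 35 with 64, and of 14 without either WT array and 9 without either KO array. The number of called lists was 17 to 19 with 1 array left out and 0 with an estimated correlation. Of the 18 called lists, 15 kept their call wherever the fit alone was changed, and the follicular helper, mitosis and glycolysis lists did not. By fry the interferon, DNA replication, mitosis, unfolded protein response and myeloid lists also lost theirs. Lists not called in the first place passed in some settings. These were TGF-beta without WT array 1 (adjusted p = 0.0497), WT array 2 (0.0495) or KO array 1 (0.0244) and by fry (0.0276), p53 with no filter (0.0261), quantile normalization (0.0495) and fry (0.0494), B and plasma cells with the 60% filter (0.0422) or without WT array 2 (1.64e-05) or KO array 2 (0.0467), and sterol synthesis without KO array 2 (0.0273). With all called-higher genes, the median ratio of the KO arrays was 0.644 for neutrophil, mast and myeloid genes and 0.213 for Th1 and cytotoxic genes, instead of 0.644 and 0.325. For Treg signature and Th2 genes it changed sign, to -0.118 from 0.164 and to 0.024 from -0.019. The share of mature B cell genes turned from below to above that of other genes without WT array 2 (9.09%), the plasma cell share no longer passed without WT array 1 (23.1%), and the innate-like T cell share passed with no filter (25%) or without WT array 1 (30%). The gap between correlations within and between genotypes, 0.041, was 0.036 with a pseudocount of 64, 0.022 with no filter, 0.064 with the 60% filter and 0.039 to 0.046 with 1 array left out. The direction of the list test reversed for 7 lists, and the cause was not tested. For NF-kappaB this happened with quantile normalization (median 0.046), no intensity trend (0.018), no cross-hybridising probe sets (-0.025), no WT array 1 (-0.098), the mean of a gene's probe sets (0.013) and fry (0.018). Leaving out single arrays gave medians up to 0.167 (no WT array 2). It happened for the ATF4 response without cross-hybridising probe sets (-0.102), for B and plasma cells without WT array 1 (-0.244, against 1.007 without WT array 2). So it did for fatty acid oxidation without WT array 2 (0.037) or KO array 2 (0.043, against 0.014 without KO array 1), for sterol synthesis without KO array 1 (0.077, against -0.290 without KO array 2), for mitosis without KO array 2 (-0.008, against -0.468 without KO array 1), and for T cell identity with the mean of probe sets (-0.154).

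With the replicate block, in which the array number is a term of the fit, 5382 probe sets were called (2412 higher, 2970 lower) and 19 lists, TGF-beta among them (adjusted p = 0.042), with 4598 of the 4608 calls kept. The labels do not say that a number marks shared mice or days. The deviations of the same-numbered arrays correlated at 0.010 across probe sets, so no pairing by number was seen over the probe sets as a whole. This cannot exclude a shared source that affects few genes. A fit with crossed pairs was not tried.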

Other observations

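The 3 patterns were picked after the results were seen. The tests of the ratio between the KO arrays and of mature B cell genes were chosen only after the result was seen, and the other test lists and their bounds were written after the patterns but before the values of their genes were looked at. The tests with no filter, without single arrays and over all called genes were also added after seeing the data. The largest rise of all belonged to a probe set without a gene name, from 9.33 ± 2.95 to 17409.9 ± 2982, a log2 fold change of 9.42 ± 0.18 (adjusted p = 1.76e-07, limma). Of the 12 largest rises over all called probe sets, 4 had no single gene name. Several further genes were singled out after their values were seen. The granzyme gene Gzmc rose from 479 ± 128 to 9955 ± 2613, the gamma-delta T cell receptor gene Trgv4 from 392.3 ± 31.0 to 1613 ± 3.60, and the eosinophil peroxidase gene Epx from 26.5 ± 14.5 to 1093 ± 904, the last with a call that was lost without the intensity trend. Of 6 tested Ighm probe sets 3 were called higher and 3 were not called, the lowest at a log2 fold change of -0.04. The largest of the rises was from 1063 ± 342 to 15394 ± 5101. There were also 2 probe sets with several immunoglobulin kappa names that rose, by log2 fold changes of 4.67 ± 0.60 and 3.19 ± 0.56, calls that were lost without the intensity trend. Leaving out single arrays moved the folds of these 2 probe sets and of Epx by over 1.5 times. The unnamed probe set with the largest rise was near the floor in WT cells, so the size of its fold depends on the pseudocount. Its log2 fold change was 10.74 with a pseudocount of 1 and 7.89 with 64, and that of Epx was 5.12 and 3.42.

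For the first pattern, the rise of mast cell genes, a candidate explanation is admixture of mast cells or basophils in the KO cultures, since the labels do not say how the naive cells were purified. Of a list of 24 other genes of these cells, 19 were tested and 57.9% called higher (11, among them Cma1 and Csf2rb, against 10.4% of other genes, one-sided Fisher exact p = 5.4e-07), which meets the bound of 50% set beforehand. With no filter it was 45.5% (10 of 22, against 5.54%, Fisher exact p = 9.86e-08), and 47.4% without WT array 1 or KO array 1, so the enrichment holds and the bound does not. Of that list Mitf, Tpsb2, Hpgds, Spi1, Hs3st1, Enpp3, Syk and Btk were not called. Mitf, Tpsb2, Hpgds and a dim Kit probe set were near the floor in both groups. A bright Kit probe set was not called, and Gata1 fell (-1.20 ± 0.17, adjusted p = 0.00202, limma). The bright Kit probe set and Gata1 had WT signals that could hide an admixed share, so neither excludes it, and the fall of Gata1 does not point to it. Tpsb2 (52.5 in WT and 47.9 in KO cells), Hpgds (55 and 55.3) and Mitf (83.5 and 72.8) had no bright WT signal and did not rise. That does not point to admixed mast cells either, but signals near the floor cannot decide it. Neutrophil, mast and myeloid genes called at a log2 change of 1 or more had a median log2(KO1/KO2) above the WT level of 0.644 over 21 genes (684 other genes, 0.117; all 23 called, 0.644), but this compares 2 single cultures and cannot tell unequal admixture from other differences, and expression by the KO T cells stays open as untested.

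For the second pattern, the rise of immunoglobulin genes, 0 of 11 tested genes of mature B cells were called higher. All 11 are on the B and plasma cell list, whose results had been seen, so this count was known in advance. It therefore cannot argue against mature B cells as a source. The largest log2 fold change of the 11 genes was 0.92 (Blk), against 3.35 for Ighm, so none of them rose as Ighm did. Single WT arrays set some of the values, as for Ms4a1 (203.1 ± 199.0 in WT and 127.7 ± 28.9 in KO cells). The median log2 fold change of the 11 genes was 0.021 with all arrays, 0.859 without WT array 2 and -0.410 without WT array 1. Without WT array 2 Blk was at 1.42, against 3.76 for Ighm. For plasma cells 38.5% of the test list was called higher (5 of 13 tested and 15 listed, against 10.4% of other genes, one-sided Fisher exact p = 0.00781), including Mzb1 and Sdc1, and 28.6% with no filter, while Txndc5, Sec11c and Derl3 were not called and Glcci1 was lower. Both values lie between the bounds set beforehand, 50% and 20%, so plasma cell admixture and a change within the T cells cannot be told apart.

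For the third pattern, the rise of cytotoxic and NK cell genes, 30% of the test list of innate-like T cells was called higher (3 of 10 tested and 22 listed, one-sided Fisher exact p = 0.0783), namely Cd160, Ckb and Itga1, and 25% with no filter (3 of 12, Fisher exact p = 0.0261), while Cd7 was lower. For NK cells 40% was called higher (2 of 5 tested and 15 listed, one-sided Fisher exact p = 0.0883), namely Cd244a and Serpinb9b, and 8.33% with no filter (1 of 12, Fisher exact p = 0.498). The added members were dim, so the lower shares exclude nothing, and few of the listed genes could be tested. Neither source can be told apart from expression in the KO T cells. A larger share of CD8 T cells in the KO cultures was not tested with a list of its own and stays open. Cd8a rose 3.43-fold and Cd8b1 2.03-fold, and 6 of 7 tested CD8 T cell markers rose, though 4 of the 7 are on other lists as well.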
